A study of Mus musculus with 18 samples.

How the data were processed

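Messenger RNA, ribosome-protected fragments and acetylated RNA were measured in TC1 cells, unedited or carrying a guide against Nat10 or Myc. The sgNAT10 and sgMyc mRNA sets each had their own WT libraries and were never pooled, except in the test of the difference between the edits. The notes of the authors name FastQC, Trim Galore, Bowtie2, featureCounts and the mouse build mm10, without versions and without saying which file each step made. Per the file headers, the sgMyc table holds a count and an FPKM value (fragments per kilobase of gene and 1 M mapped fragments) per gene and library for 28738 genes. The ratio of count to FPKM differed between libraries by a single factor per library, to within 1%, in at least 97.5% of genes. The gene positions of that table are not those of mm10, since 4.2% of 22068 genes started within 5 kb of their position there, so positions from it served only to find the nearest neighbours of genes within that table. Per the file headers, the sgNAT10 mRNA and Ribo-seq tables hold FPKM for 17379 and 10974 genes with log2 fold changes and p-values of the authors, whose test is not named. The authors' table lists 3923 genes higher and 3776 lower in sgNAT10 mRNA and 818 and 840 in Ribo-seq at an adjusted p-value under the threshold of 0.05. The acRIP table as deposited lists peaks with a fold enrichment of precipitate over input, a log2 fold difference between genotypes and scores, each score being a log10 p-value or FDR as the header states. The header does not say which genotype is on top of that fold, which was read as sgNAT10 over WT. Of 1268 peaks in genes with a known position, 99.0% lay inside their gene on mm10.

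The tests, gene lists, groups and rules were fixed before the data were examined. For the sgNAT10 mRNA and Ribo-seq sets, log2(FPKM + 1) was tested with limma 3.58.1 (R 4.3.3; lmFit, eBayes with a trend) in genes with a mean of at least 1 FPKM. Translational efficiency was the genotype by assay interaction in 1 limma model of both assays. That model took 1 residual spread per gene for both assays. Ribo-seq replicates spread more, with a common coefficient of variation of 0.352 against 0.0228 in mRNA. Its standard errors and p-values can therefore understate the error of the footprints. The sgMyc set was tested on counts with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Whole reads were recovered from the ratios of FPKM between libraries, as the smallest whole numbers that gave these ratios to within 1e-09, in 99.9% of genes in the mRNA table and 99.98% in the Ribo-seq table. They gave the depth, which is too low where all reads of a gene share a divisor, and an alternative test.

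The 22 gene lists were interferon-stimulated genes, nucleic acid sensing and interferon signalling, MHC class I presentation, MYC targets, G1/S and DNA replication, G2/M, DNA methylation and transposon silencing, chemokines with cytokines and checkpoint ligands, CDK regulators, ribosome biogenesis, ribosomal proteins, p53 targets, ATF4 and the integrated stress response, glycolysis, oxidative phosphorylation and extracellular matrix. They also held markers of T cells, macrophages, endothelium, epithelium and fibroblasts, and the mitochondrially encoded genes as a sign of RNA quality. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance without comparing it with other genes, were alternatives.

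Genes were named by a rule: the 4 title genes everywhere; the 6 largest changes each way (4 each way for translational efficiency) among genes past the test whose genotypes did not overlap and whose higher mean was at least 5 FPKM, leaving out predicted genes; up to 3 members of each list fixed as primary and 2 of each other list, and every tested marker. Where no list member passed, those with the lowest p are given as values. Some genes and peaks that the rule names are left out of the text. Per-library values of Isg15, Ifnb1, Col3a1, Dcn, Cd68 and Cd14, and Rack1, Ybx1 and Sulf2, were chosen after their values were seen. The difference between the edits was tested with limma on both mRNA sets in 1 model with a term for the set, chosen after the data were seen. Overlaps of called genes used two-sided Fisher's exact tests over the genes tested in both comparisons. Peak genes were compared with 10000 random gene lists matched on mean expression in 10 bins (seed 1). The acRIP peaks were described without a test of their own, for want of replicates. A fold against a group at 0 was taken over 3 counts per group. Alternatives covered pseudocounts, filters, scalings, other tools (DESeq2 1.42.0), a block for the replicate number and leaving out each library in turn. Where that left 1 library in a group, its spread was taken to be that of the others. Library numbers did not pair the libraries.

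The tests were tried on simulated data with the spread and depth of each set. Of genes changed 2-fold and 4-fold, limma recovered 88.8% and 98.9% in mRNA and 0% and 43.8% in Ribo-seq, the interaction 6.29% and 49.7%, and edgeR in the sgMyc set 46% and 87.9%. False calls numbered 19, 4, 9 and 7, and camera called 0 of 100 unchanged lists in the mRNA and sgMyc simulations. The simulated genes were drawn independently of each other, so this does not show how camera behaves where genes of a list are correlated. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.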

Results

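The data came from TC1 cells, a mouse tumour line that the labels describe as fibrosarcoma, either unedited (WT) or carrying a guide RNA against Nat10 (sgNAT10) or against Myc (sgMyc). Messenger RNA was sequenced in 2 sets with separate controls, 2 WT and 2 sgNAT10 libraries in the first and 3 WT and 3 sgMyc libraries in the second. Ribosome-protected RNA fragments (Ribo-seq) were sequenced from 2 WT and 2 sgNAT10 libraries. Acetylated RNA was immunoprecipitated (acRIP-seq) with 1 precipitated and 1 input library for each of WT and sgNAT10. No library carried a control guide, so each edit was compared with unedited cells only. The counts of the sgMyc set summed to 55754427, 51875052 and 55900895 in WT and 58462340, 57363229 and 65768024 in sgMyc. Reads recovered from the FPKM values summed to 15081832 and 12614933 in WT and 12301856 and 11515292 in sgNAT10 for mRNA. For Ribo-seq they summed to 2743627 and 2694834 in WT and 3148083 and 1514086 in sgNAT10. Values per genotype are the mean ± SD of the FPKM, with n = 2 in the sgNAT10 mRNA and Ribo-seq sets and n = 3 in the sgMyc set. Log2 fold changes are edited over WT with their standard errors. In the edgeR test of the sgMyc set, these errors were worked back from the fold change and the p-value of the F test.

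The series title names 4 genes, and these were followed in every comparison. Nat10, the enzyme that acetylates cytidines in RNA, had 5.33 ± 0.0437 FPKM of mRNA in WT and 3.77 ± 0.258 in sgNAT10. That is a fall of 0.41 on the log2 scale (log2 fold change -0.41, SE 0.0593, adjusted p = 0.00266). Myc, a transcription factor that drives cell growth, fell from 116 ± 1.26 to 40.5 ± 0.664 (log2 fold change -1.49, SE 0.0293, adjusted p = 9.4e-06). Cdk2, a kinase of entry into S phase, fell from 9.22 ± 0.0298 to 7.76 ± 0.137 (-0.22, SE 0.041, adjusted p = 0.00631). Dnmt1, the enzyme that copies DNA methylation to new strands, rose from 30.6 ± 0.733 to 37.9 ± 1.4 (0.30, SE 0.0401, adjusted p = 0.00195). In Ribo-seq Myc fell from 281 ± 0.135 to 103 ± 32.4 (-1.47, SE 0.225, adjusted p = 0.0298), while Nat10 had 14.6 ± 3.88 in WT and 7.46 ± 1.22 in sgNAT10 and did not pass (-0.87, adjusted p = 0.193). Cdk2 (0.23, adjusted p = 0.649) and Dnmt1 (0.03, adjusted p = 0.939) did not pass in Ribo-seq either. In the sgMyc set Myc fell from 65.7 ± 4.65 to 25.4 ± 7.55 (-1.37, SE 0.219, adjusted p = 0.011), Cdk2 from 42.0 ± 4.1 to 11.8 ± 0.636 (-1.83, SE 0.105, adjusted p = 0.000554) and Dnmt1 from 102 ± 7.84 to 55.3 ± 6.56 (-0.88, SE 0.121, adjusted p = 0.00666). Nat10 had 5.001 ± 0.133 in WT and 4.37 ± 1.65 in sgMyc and did not pass (-0.19, SE 0.26, adjusted p = 0.675). Every passing gene of the 4 was lower, or in Dnmt1 of the sgNAT10 set higher, in all edited libraries than in all WT libraries of its set.

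Some of these calls were lost with fewer libraries or under another setting. With all Ribo-seq libraries, limma without a trend in the variance did not call Myc (log2 fold change -1.47, adjusted p = 0.134). The Ribo-seq call of Myc was lost without WT replicate 1 (adjusted p = 0.186), WT replicate 2 (0.192), sgNAT10 replicate 1 (0.304) or sgNAT10 replicate 2 (0.185), with a log2 fold change between -1.80 and -1.15. The sgMyc call of Myc was lost without WT replicate 1 (log2 fold change -1.38, adjusted p = 0.0566), WT replicate 2 (-1.42, 0.0519) or WT replicate 3 (-1.31, 0.0658), with little change in the fold. Without sgMyc replicate 3, Nat10 was lower in sgMyc by 0.52 on the log2 scale (log2 fold change -0.52, adjusted p = 1.0e-04).

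**Figure D1:**
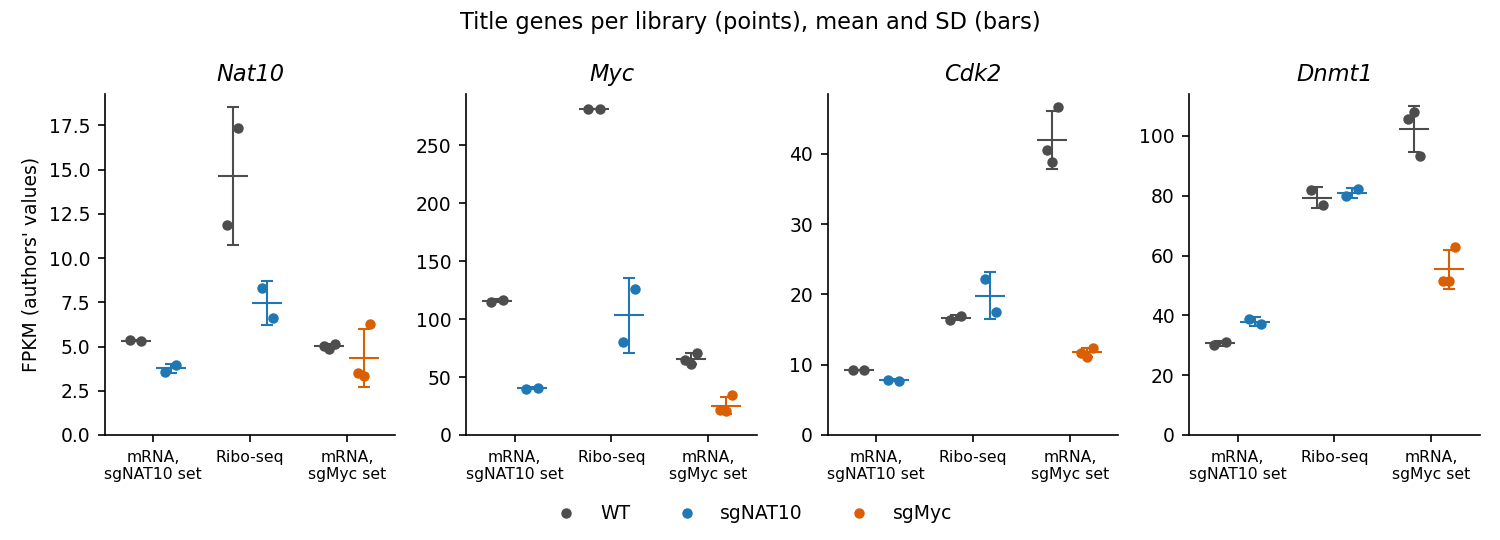
FPKM (vertical axis, from 0) of Nat10, Myc, Cdk2 and Dnmt1 in each library, shown as points, with the mean and SD of each genotype as a dash and bar. Dnmt1 mRNA averaged 37.9 in sgNAT10 against 30.6 in its WT and 55.3 in sgMyc against 102 in its WT.

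The first comparison asked what the Nat10 guide did to mRNA levels. Grem1, a secreted antagonist of bone morphogenetic proteins, rose from 2.64 ± 0.574 to 170.0 ± 2.29 FPKM in sgNAT10. Sgk1, a kinase induced by serum and glucocorticoids, rose from 1.87 ± 0.118 to 62.9 ± 2.7, and Ptgs2, a prostaglandin synthase, from 1.48 ± 0.108 to 48.4 ± 0.176. The small heat shock protein gene Cryab rose from 2.49 ± 0.594 to 69.8 ± 2.97, the surface glycoprotein gene Thy1 from 1.19 ± 0.219 to 41.8 ± 1.23, and the extracellular superoxide dismutase gene Sod3 from 0.0547 ± 0.0256 to 19.4 ± 0.22. Crabp1, which binds retinoic acid, fell from 226 ± 4.72 to 0.557 ± 0.133, and Bgn, a matrix proteoglycan, from 180 ± 1.17 to 0.872 ± 0.112. Ctsz, a lysosomal protease, fell from 34.3 ± 0.777 to 0.291 ± 0.0136, the kinase gene Rps6ka6 from 22.2 ± 0.125 to 0.0842 ± 0.0208, and Cyba, a subunit of NADPH oxidases, from 23.3 ± 0.407 to 0.201 ± 0.0314. Ppic, a prolyl isomerase, fell from 17.4 ± 0.278 to 0.0949 ± 0.0703. The largest adjusted p among these 12 genes was 1.7e-05. Of 11735 genes tested with limma, 7431 passed, 3960 higher and 3471 lower in sgNAT10, of which 553 rose and 297 fell by 1 or more on the log2 scale. The excess of higher genes depended on the processing, with 3464 higher and 3992 lower after quantile normalization and 4342 and 4290 without a filter on low values. With edgeR on recovered reads, which changed the tool, the input and the filter at once, it was 4621 and 4629. That test was added after the data were seen. Replicates of a genotype differed little more than sampling allows, with 0.763% of genes in the WT pair and 1.46% in the sgNAT10 pair past a chi-square limit that sampling alone exceeds in 0.1%, so the test measured a spread close to that of repeated sequencing.

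Growth genes fell together in sgNAT10. Of 57 targets of MYC tested, 40 fell and 7 rose (40 and 8 adjusted over the list alone), with a median log2 fold change of -0.38. Sord, which converts sorbitol, fell from 46.5 ± 1.4 to 4.97 ± 0.357 FPKM, the nucleolar genes Nolc1 from 75.5 ± 0.622 to 38.4 ± 0.226 and Npm1 from 875 ± 15.9 to 480 ± 2.04. Of 40 genes of ribosome biogenesis, 30 fell and 1 rose (31 and 1 adjusted over the list alone; median -0.24), among them Polr1c (-0.97) and Nol11 (-0.62). Of 74 ribosomal protein genes, 48 fell and 4 rose (49 and 4 adjusted over the list alone; median -0.22), with Rpl13a (-0.97) and Rpl5 (-0.67) falling most. Of 17 glycolysis genes, 11 fell and none rose (11 adjusted over the list alone; median -0.15, and down to -0.25 with another scaling or tool), including the phosphofructokinase gene Pfkp (-1.19) and the lactate transporter gene Slc16a1 (-0.55). Against other genes, camera gave adjusted p = 6.5e-07 for the MYC targets, 3.6e-06 for ribosome biogenesis, 4.6e-07 for ribosomal proteins and 0.00496 for glycolysis. No list passed with an estimated correlation between genes: adjusted p = 0.249 with an estimated correlation for MYC targets and for ribosome biogenesis, and 0.69 for the other 2 lists.

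The interferon and antigen presentation genes of sgNAT10 moved both ways, and none of their lists passed camera. In fry, interferon-stimulated genes (adjusted p = 0.0319), MHC class I presentation (0.00454) and chemokines and cytokines (0.0177) passed, and nucleic acid sensing (0.179) did not. Of 13 interferon-stimulated genes with enough mRNA to test, 3 rose and 8 fell (3 and 8 adjusted over the list alone; median -0.30; camera adjusted p = 0.172). The chemokine gene Cxcl10 rose from 3.63 ± 0.0323 to 10.1 ± 0.435 FPKM, while Bst2, which tethers budding viruses, fell from 38.2 ± 0.625 to 15.7 ± 1.47 and the ubiquitin ligase gene Dtx3l from 2.61 ± 0.0611 to 0.693 ± 0.0618. Of 17 genes of nucleic acid sensing and interferon signalling, 5 rose and 8 fell (6 and 8 adjusted over the list alone; median 0.09, mean -0.01; camera adjusted p = 0.908), with the STING gene Tmem173 at -1.32, the ubiquitin ligase gene Trim25 at -0.96 and the kinase gene Jak1 at 1.21. Of 17 genes of MHC class I presentation, 6 rose and 8 fell (6 and 8 adjusted over the list alone; median -0.03; camera adjusted p = 0.774). The peptide transporter gene Tap2 (-1.69) and the immunoproteasome gene Psmb10 (-1.46) fell, and the MHC gene H2-Q4 rose (0.96). Of 13 genes of chemokines, cytokines and checkpoint ligands, 4 rose and 7 fell (4 and 7 adjusted over the list alone; median -0.52; camera adjusted p = 0.325), with Ptgs2 at 4.32, the chemokine gene Cx3cl1 at 1.80 and the growth factor gene Tgfb2 at -1.63.

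Cell cycle, chromatin and stress lists of sgNAT10 did not pass camera as groups. Of 39 genes of G1/S and DNA replication, 11 rose and 12 fell (11 and 12 adjusted over the list alone; camera adjusted p = 0.89): the licensing gene Cdt1 (-0.80) was among those that fell, and the transcription factor gene E2f1 rose (0.91). Of 30 genes of G2/M, 11 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.186), with the cytokinesis genes Prc1 (0.72), Anln (0.66) and Kif20a (0.45) rising. Of 18 regulators of CDKs, 8 rose and 7 fell (10 and 7 adjusted over the list alone; adjusted p = 0.908); the inhibitor gene Cdkn1a fell (-1.26) and the inhibitor gene Cdkn2d rose (0.81). Of 29 genes of DNA methylation and transposon silencing, 11 rose and 8 fell (11 and 8 adjusted over the list alone; adjusted p = 0.908), with the histone methyltransferase gene Ehmt2 (1.02) and the demethylase gene Kdm1a (0.74) rising and Tet3, which oxidises methylcytosine, falling (-0.70). Of 19 targets of p53, 7 rose and 6 fell (7 and 6 adjusted over the list alone; median -0.09, mean 0.03; adjusted p = 0.908), Cdkn1a being the largest fall and the kinase gene Plk2 (0.86) the largest rise. Of 22 genes of ATF4 and the integrated stress response, 8 rose and 11 fell (9 and 11 adjusted over the list alone; median -0.04, mean 0.02; adjusted p = 0.774), with the folate enzyme gene Aldh1l2 at 1.69 and Ddit4, an inhibitor of mTOR, at -1.35. The direction of this last list was up in fry (adjusted p = 0.0325). G2/M also passed in fry (adjusted p = 0.00753). Of 28 genes of oxidative phosphorylation, 2 rose and 12 fell (2 and 11 adjusted over the list alone; adjusted p = 0.0604), among them Uqcrfs1 and Ndufv1 (both -0.55); the list passed without sgNAT10 replicate 1 (adjusted p = 0.0405), with a minimum mean of 5 FPKM (0.0386), with median scaling (0.0454) and in fry (0.0298). Of 18 genes of extracellular matrix, 11 rose and 4 fell (11 and 4 adjusted over the list alone; median 0.59; adjusted p = 0.0801), with the matrix glycoprotein gene Thbs1 at 3.41; the list passed with a minimum mean of 5 FPKM (adjusted p = 0.0364) and in fry (0.00659).

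Markers of other cell types and of RNA quality were read in the same libraries. Of 5 fibroblast markers tested in the sgNAT10 mRNA set, Thy1, Pdgfra (2.18) and Col1a2 (1.61) rose and Pdgfrb (-0.46) and Col3a1 (-0.27) fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.325). Of 3 macrophage markers, Cd14, a coreceptor for bacterial lipopolysaccharide, rose (1.71; 1 rose adjusted over the list alone), while Csf1r (-0.16, adjusted p = 0.125) and Cd68 (0.04, adjusted p = 0.838) did not pass. No T cell, endothelial or epithelial marker reached the mean of 1 FPKM needed for the test. Of 13 mitochondrially encoded genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.43; adjusted p = 0.191), and the list passed without WT replicate 2 (adjusted p = 0.0435). The ribosomal RNA locus Gm23935 held 22.6% and 22.0% of the summed FPKM in WT and 23.1% and 35.8% in sgNAT10.

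The second comparison asked which RNAs carried more or fewer ribosomes in sgNAT10. Cryab rose from 0.643 ± 0.91 to 137 ± 1.75 FPKM of footprints, Il1rl1, an interleukin receptor, from 2.66 ± 0.71 to 128 ± 0.484, and Sgk1 from 7.01 ± 0.0528 to 270.4 ± 15.2. Grem1 rose from 2.83 ± 0.0013 to 143 ± 15.7, Sod3 from 0.511 ± 0.477 to 41.4 ± 5.25, and U90926 from 0.198 ± 0.28 to 50.3 ± 8.76. Crabp1 fell from 405 ± 62.3 to 4.13 ± 3.36, Bgn from 220.1 ± 38.7 to 1.56 ± 0.0615 and Ctsz from 57.9 ± 2.53 to 0.499 ± 0.431. The linker histone gene Hist1h1a fell from 102 ± 16.7 to 1.17 ± 1.66, the core histone gene Hist4h4 from 38.1 ± 0.561 to 0.0489 ± 0.0692, and the homeobox gene Esx1 from 42.2 ± 2.52 to 0.0706 ± 0.0998. The adjusted p of these 12 genes lay between 0.000482 and 0.00914. Of 9707 genes tested with limma, 300 passed, 176 higher and 124 lower, of which 158 rose and 109 fell by 1 or more on the log2 scale. Without WT replicate 1, 9 genes passed, and without WT replicate 2, 7 did. Without sgNAT10 replicate 1 or replicate 2 limma called 0 genes, with 1175 and 1211 at an unadjusted p under the threshold of 0.05. Without a trend in the variance 87 genes passed, and edgeR on recovered reads, added after the data were seen, called 777 genes over all 4 libraries. Of 31 genes named from this comparison, 7 still passed without WT replicate 1, 5 without WT replicate 2, and 0 without either sgNAT10 replicate.

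Several gene groups were lower in the sgNAT10 footprints. Of 7 mitochondrially encoded genes tested, 6 fell and none rose (7 adjusted over the list alone), with a median log2 fold change of -2.24. Among them mt-Co1, a subunit of cytochrome oxidase, fell from 165.2 ± 7.32 to 13.998 ± 1.23 FPKM, and mt-Nd2, a subunit of respiratory complex I, from 153 ± 7.71 to 19.1 ± 7.3. The MYC targets had a median of -0.42: 3 of 58 fell and none rose (11 fell and 1 rose adjusted over the list alone), namely Nolc1 (-1.05) and the ribosome biogenesis genes Wdr43 (-0.85) and Nop16 (-0.85). The 40 genes of ribosome biogenesis had a median of -0.22, with none past over all genes and 7 falling adjusted over the list alone; Utp4 (-0.80, adjusted p = 0.0591) and Tsr1 (-1.04, adjusted p = 0.0594) came closest. Of 5 fibroblast markers, the collagen gene Col1a2 (1.61), Thy1 (2.31) and the growth factor receptor gene Pdgfra (1.90) rose (3 adjusted over the list alone; median 1.61). Camera gave adjusted p = 2.7e-07 for the mitochondrial genes, 0.000497 for the MYC targets, 0.016 for ribosome biogenesis and 0.016 for the fibroblast markers; each had adjusted p = 0.446 with an estimated correlation. The fibroblast call was lost without WT replicate 2 (adjusted p = 0.112) or sgNAT10 replicate 1 (0.0508), and that of ribosome biogenesis without sgNAT10 replicate 1 (0.0881).

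Other lists of the footprints did not pass camera. Of 17 interferon-stimulated genes, the exonuclease gene Isg20 fell (-2.46) and none rose (1 each way adjusted over the list alone; median -0.66; adjusted p = 0.0667), and the list passed without sgNAT10 replicate 2 (adjusted p = 0.0323). Of 16 genes of nucleic acid sensing, Jak1 rose (1.24; 1 each way adjusted over the list alone; adjusted p = 0.697). Of 16 genes of MHC class I presentation, H2-D1 (0.87) and B2m (0.60), the heavy and light chains of a class I molecule, rose and Tap2 fell (-3.55; 3 each way adjusted over the list alone; adjusted p = 0.607). Of 13 genes of chemokines and cytokines, Ptgs2 rose (4.40) and the chemokine gene Ccl2 fell from 918 ± 38.2 to 329 ± 10.2 FPKM (1 rose and 2 fell adjusted over the list alone; median -0.10, mean 0.15; adjusted p = 0.906). None of 39 genes of G1/S (adjusted p = 0.906), of 30 of G2/M (0.337), of 28 of oxidative phosphorylation (0.337) or of 17 of glycolysis (0.182) passed over all genes. Adjusted over the list alone, 0, 0 and 0 passed in the first 3 and 1 rose and 3 fell in glycolysis; the lowest p of the last 3 lists named belonged to Prc1 (0.59, adjusted p = 0.147), the oxidase subunit gene Cox5b (-1.04, 0.0659) and Pfkp (-1.28, 0.0606). Of 18 regulators of CDKs, Cdkn2d rose (2.41) and Cdkn1a fell (-1.36; 3 rose and 1 fell adjusted over the list alone; adjusted p = 0.652). Cdkn1a was also the 1 of 18 p53 targets that fell (1 adjusted over the list alone; adjusted p = 0.658). Kdm1a rose (1.13) among 26 genes of DNA methylation and silencing (1 adjusted over the list alone; adjusted p = 0.658), and the transcription factor gene Cebpb (1.15) among 24 of ATF4 and stress (3 each way adjusted over the list alone; median -0.09, mean 0.04; adjusted p = 0.963). Of 74 ribosomal protein genes, 1 fell, Rps29 (-0.81), and 1 rose (1 fell and 0 rose adjusted over the list alone; adjusted p = 0.689). Of 21 genes of extracellular matrix, 4 rose and 2 fell (6 and 4 adjusted over the list alone; adjusted p = 0.653), with Thbs1 at 3.33. The macrophage markers Cd68 and Cd14 and the epithelial marker Krt18 were tested and did not pass, and no T cell or endothelial marker reached the minimum.

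The third comparison set footprints against mRNA, asking which RNAs changed their ribosome load relative to their amount, the translational efficiency. Ribosomal protein genes carried more footprints per mRNA in sgNAT10: 62 of 74 had a positive change, with a median of 0.29 on the log2 scale. Their footprints had a median change of 0.01, with 38 of 74 positive, and their mRNA one of -0.22, so the rise of the ratio lay on the side of the mRNA. Of these, 3 passed over all genes, and 27 rose and 2 fell adjusted over the list alone, with Rps24 at 0.85 (SE 0.1, adjusted p = 0.0416) and Rps19 at 0.76 (SE 0.093, adjusted p = 0.0485). The 7 mitochondrially encoded genes all had a negative change (median -2.10), of which mt-Co1 passed over all genes (-3.01, SE 0.131, adjusted p = 0.00129) and 7 fell adjusted over the list alone. That SE is smaller than the SE of 0.174 of the Ribo-seq change of mt-Co1 alone, since the model took 1 spread for both assays. The adjusted p-values of translational efficiency can thus be too low. Camera gave adjusted p = 1.4e-09 for ribosomal proteins and 1.3e-09 for mitochondrial genes, and adjusted p = 0.199 and 0.288 with an estimated correlation. Among single genes the small nuclear RNA exonuclease gene Usb1 (1.73) and the small nucleolar RNA host gene Gas5 (1.13) rose. Tmem203 and Mapk1ip1 also passed but had 0 FPKM of footprints in WT, against 24.7 and 7.04 in sgNAT10, so that the size of their change depends on the pseudocount. After mt-Co1 the largest falls fitted were in Gatad1 (-2.41), the histone variant gene H2afx (-2.22) and Tmem18 (-2.11), and the polyamine synthesis gene Odc1, a MYC target, fell by 1.68 (-1.68, adjusted p = 0.0317; 1 fell adjusted over the list alone). None of the title genes passed: Nat10 had -0.46 (adjusted p = 0.615), Myc 0.02 (0.99), Cdk2 0.45 (0.448) and Dnmt1 -0.27 (0.4).

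Of 9200 genes tested, limma called 24, 14 higher and 10 lower in translational efficiency. Leaving out 1 mRNA library left 3 genes past without WT replicate 1, WT replicate 2 or sgNAT10 replicate 2 and 6 without sgNAT10 replicate 1, whereas leaving out 1 Ribo-seq library gave 473 and 640 genes without WT replicates 1 and 2 and 190 and 132 without sgNAT10 replicates 1 and 2. With the assays fitted apart 299 genes passed, and with the replicate number as a block 1 gene did. The counts with a library left out cannot show how stable the calls are, since the model took 1 spread per gene for both assays. Without a Ribo-seq library that spread rests more on the mRNA libraries, whose replicates differed less. Outside ribosomal proteins, mitochondrial genes and MYC targets (57 tested, camera adjusted p = 1.00) no list had a gene past over all genes tested. Camera gave adjusted p = 0.703 for the 13 interferon-stimulated genes (Isg20 -1.48, adjusted p = 0.0529; 2 fell adjusted over the list alone), 0.703 for CDK regulators (1 rose adjusted over the list alone), 0.73 for extracellular matrix, and 1.00 for MHC class I presentation (1 fell adjusted over the list alone), glycolysis (1 rose adjusted over the list alone) and fibroblast markers (1 fell adjusted over the list alone). It gave 1.00 for nucleic acid sensing, G1/S, G2/M, DNA methylation, ribosome biogenesis, p53 targets, ATF4, oxidative phosphorylation and chemokines, with 0 genes past adjusted over the list alone in each. The 2 macrophage markers did not pass. The median, mean and camera direction of a list differed in sign in G1/S (median -0.04, mean 0.01), G2/M (-0.08 and 0.02), p53 targets (-0.04 and 0.06), DNA methylation (0.00 and -0.03), ribosome biogenesis (0.00 and 0.02, camera down), oxidative phosphorylation (0.03 and -0.02), fibroblast markers (0.01 and -0.27) and ATF4 (-0.02 and -0.05, camera up).

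The fourth comparison asked what the Myc guide did to mRNA levels, against its own controls. Interferon-stimulated genes rose: 39 of 43 passed and none fell (42 rose adjusted over the list alone), with a median log2 fold change of 5.45, or 5.45 with the 1 gene at 0 in WT set to its bound. Ifi44 rose from 0.0927 ± 0.028 to 66.7 ± 55.5 FPKM, the antiviral synthetase gene Oas2 from 0.0224 ± 0.00733 to 20.3 ± 16.9, and the antiviral enzyme gene Rsad2 from 0 to 4.43 ± 3.63 (6.80, 6.23 and 0.245 in replicates 1, 2 and 3), at least 1116-fold higher. The interferon-inducible GTPase genes Iigp1, Tgtp2 and Gbp6 rose from 0.00326 ± 0.00565, 0.00613 ± 0.0106 and 0.00666 ± 0.0115 to 7.88 ± 6.7, 11.7 ± 9.89 and 9.19 ± 7.78, and the schlafen genes Slfn8 and Slfn2 from 0.0233 ± 0.0144 and 0.0129 ± 0.0224 to 20.7 ± 16.9 and 10.8 ± 8.83. The 3 sgMyc libraries differed: all 43 genes lay above the highest WT library in sgMyc replicates 1 and 2 and 40 of 43 in replicate 3, where chance gives 25%. Their median difference from the WT mean in log2(FPKM + 1), which shrinks genes of low expression and is not on the scale of the fitted 5.45, was 4.56 and 4.50 in replicates 1 and 2 and 0.96 in replicate 3. Isg15, a ubiquitin-like modifier, had 6.37, 4.46 and 6.74 FPKM in WT and 574, 559 and 40.5 in sgMyc replicates 1, 2 and 3, and Ifnb1, the interferon beta gene, had 0, 0 and 2 counts in WT and 67, 48 and 4 in sgMyc. Camera gave adjusted p = 8.8e-17 for the list, and adjusted p = 0.664 with an estimated correlation. Of the lists in sgMyc, fry called only the mitochondrially encoded genes (adjusted p = 0.00188), and the interferon-stimulated genes did not pass in it (0.103). Without WT replicate 1, 1 member passed over all genes in edgeR, and 0 without WT replicate 2 or 3, with 41 past adjusted over the list alone in each. Without sgMyc replicates 1, 2 and 3 it was 17, 16 and 44. With the replicate number as a block 10 of 44 passed, with the limma settings 13 to 21 of 42, and with DESeq2 43 of 44. The lowest median over these settings was 3.395 with limma.

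**Figure D2:**
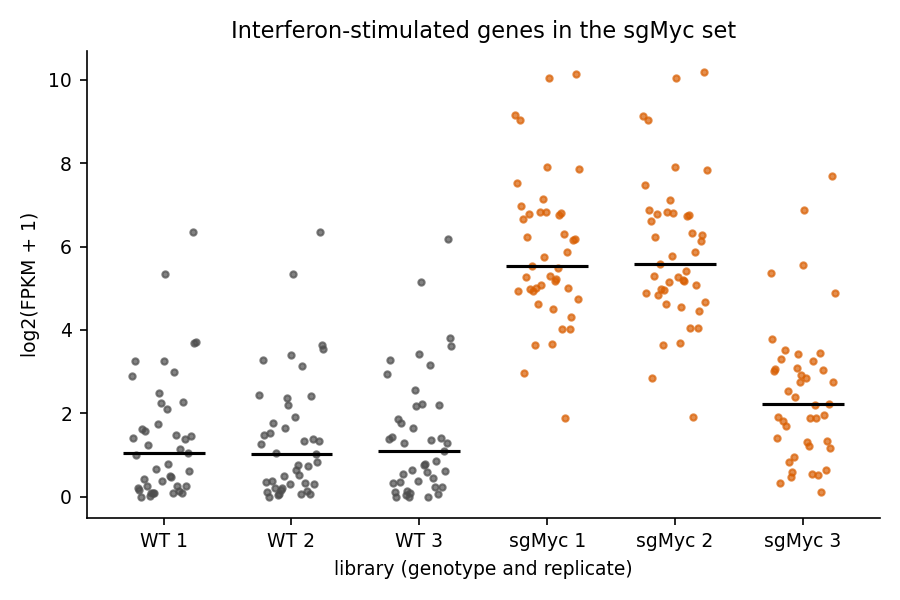
Level of each of the 43 interferon-stimulated genes, as log2 of FPKM plus 1 (vertical axis), in the 6 libraries of the sgMyc set. Points are genes and lines are medians over genes, and the median FPKM was 45.4 and 47.3 in sgMyc replicates 1 and 2 and 3.66 in replicate 3.

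The same 6 libraries held falls to near 0. Tspan6, a tetraspanin gene, fell from 6.16 ± 0.589 FPKM to 0 in all 3 sgMyc libraries, at least 849-fold lower, and Ppic from 6.62 ± 1.22 to 0, at least 623-fold lower. Crabp1 fell from 289 ± 38.3 to 0.424 ± 0.263, Ctsz from 37.7 ± 4.4 to 0.0946 ± 0.082, the procollagen protease gene Adamts14 from 13.04 ± 1.75 to 0.0133 ± 0.00187 and Rps6ka6 from 9.13 ± 1.16 to 0.0133 ± 0.0116. The adjusted p of these 6 genes lay between 3.2e-05 and 0.0012. The bounds for Tspan6 and Ppic, like those for Rsad2 and Postn, rest on 3 counts over a group of 3 libraries and cover counting error only. Counts were not single fragments throughout, since a count of 4 was listed 2517 times in protein-coding genes against 732 times for 3 and 513 times for 5; with 4 counts to a fragment each bound would be 4 times lower.

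Of 16794 genes tested with edgeR in the sgMyc set, 2682 passed, 1194 higher and 1488 lower, of which 479 rose and 726 fell by 1 or more on the log2 scale. The balance turned with DESeq2, which called 2090 higher and 1702 lower, and with a minimum mean of 5 FPKM, with 768 and 651; edgeR with the size factors of DESeq2 gave 1330 and 1358. The count rested on sgMyc replicate 3, which stood apart from replicates 1 and 2: without it 9368 genes passed, 4658 higher and 4710 lower. It was 1225 without sgMyc replicate 1, 1134 without replicate 2, and 782, 796 and 680 without WT replicates 1, 2 and 3. With the replicate number as a block 949 genes passed, and 1419 with the minimum mean of 5 FPKM. Of 46 genes named from this comparison, 17 still passed without WT replicate 1, 17 without WT replicate 2, 17 without WT replicate 3, 23 without sgMyc replicate 1, 23 without sgMyc replicate 2 and all 46 without sgMyc replicate 3.

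Some signalling genes rose in sgMyc. Of 21 genes of nucleic acid sensing and interferon signalling, 5 rose and none fell (10 rose adjusted over the list alone; median 0.48), with the RNA editing gene Adar rising from 6.46 ± 0.147 to 33.5 ± 19.4 FPKM, Trim25 from 8.53 ± 0.307 to 39.1 ± 21.2 and Jak1 from 46.4 ± 1.93 to 73.4 ± 4.16. Of 19 genes of MHC class I presentation, none passed (0 adjusted over the list alone; median 0.79; camera adjusted p = 0.11), the lowest p belonging to Psmb10 (2.11, adjusted p = 0.0513) and the chaperone gene Pdia3 (-0.46, adjusted p = 0.0539). Of 24 genes of chemokines and cytokines, 3 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.19), with the chemokine genes Ccl5 at 2.55 and Cx3cl1 at 1.93 and Tgfb2 at -2.45. Camera gave adjusted p = 0.000387 for nucleic acid sensing, and adjusted p = 0.664 with an estimated correlation. Without sgMyc replicate 3 MHC class I presentation passed (adjusted p = 9.3e-06), as did the chemokines and cytokines (0.0023).

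Cell cycle genes fell as groups in sgMyc. Of 39 genes of G1/S and DNA replication, 8 fell and none rose (9 fell adjusted over the list alone; median -0.26), among them Cdk2 and the cyclin gene Ccne2 (-0.67). Of 30 genes of G2/M, the topoisomerase gene Top2a (-0.41) and the kinetochore gene Cenpf (-0.38) fell (0 adjusted over the list alone; median -0.26). Of 17 glycolysis genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.36), with Pfkp at -0.95 and Pgam1 at -0.62. Of 75 ribosomal protein genes, 6 fell and 1 rose (0 adjusted over the list alone; median -0.17), with Rpl17 at -1.11 and Rpl6 at -0.51. Of 21 targets of p53, 4 rose and none fell (6 rose and 1 fell adjusted over the list alone; median 0.24), with the death receptor genes Fas at 2.06 and Tnfrsf10b at 0.63. Camera gave adjusted p = 0.00162 for G1/S, 0.00601 for G2/M, 0.0144 for glycolysis, 0.00643 for ribosomal proteins and 0.0316 for p53 targets. With an estimated correlation the adjusted p = 0.783 for G1/S and G2/M, 0.664 for glycolysis and p53 targets and 0.829 for ribosomal proteins. The call of G2/M was lost without sgMyc replicate 1 (adjusted p = 0.0781) or 2 (0.0977), that of ribosomal proteins without sgMyc replicate 1 (0.142) or 2 (0.197), and that of glycolysis without sgMyc replicate 2 (0.0533). That of p53 targets was lost without WT replicate 2 (0.0502) or 3 (0.069) or sgMyc replicate 1 (0.0691) or 2 (0.0977). The size of these changes also moved when a library was left out: the median ran from -0.36 to -0.15 in G1/S, from -0.41 to -0.12 in G2/M, from -0.23 to -0.07 in ribosomal proteins and from 0.19 to 0.40 in p53 targets. With quantile normalization the median of the ribosomal proteins was -0.05.

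The MYC targets themselves depended on the setting, and most on sgMyc replicate 3. Of 58, 1 fell and none rose (1 adjusted over the list alone; median -0.15; camera adjusted p = 0.0756), namely Sord, from 17.1 ± 1.28 to 8.26 ± 0.546 FPKM. Without sgMyc replicate 3, 52 fell and 1 rose, with a median of -0.65 (camera adjusted p = 4.4e-14). The sign of the median turned without sgMyc replicate 1 (0.05) or replicate 2 (0.06), with 34 of 58 genes positive in each case. The list also passed with a minimum mean of 5 FPKM (adjusted p = 0.0128), with the replicate number as a block (0.0199), and with limma at median scaling (0.0184) or a pseudocount of 0.1 (0.0308). Of 39 genes of G1/S, 33 fell without that replicate. The Myc mRNA itself stood at 21.1 and 20.9 FPKM in sgMyc replicates 1 and 2 and 34.1 in replicate 3. Of 40 genes of ribosome biogenesis, the polymerase subunit gene Polr1c fell (-0.48) and the large subunit assembly gene Brix1 rose (0.33; 0 adjusted over the list alone; adjusted p = 0.243), and the list passed without replicate 3 (adjusted p = 2.9e-07). Of 28 genes of oxidative phosphorylation, Ndufb8 (-0.71) and Cox6c (-0.41) fell (2 adjusted over the list alone; adjusted p = 0.581; 0.00602 without replicate 3). Of 24 genes of ATF4 and stress, 4 rose and 5 fell (5 and 6 adjusted over the list alone; adjusted p = 0.19; 0.00174 without replicate 3 and 0.0172 with the minimum mean of 5 FPKM), with the transcription factor gene Atf3 at 1.82 and the pseudokinase gene Trib3 at -1.32. Of 18 regulators of CDKs, 4 fell (4 adjusted over the list alone; median 0.03, mean -0.06; adjusted p = 0.679), with the retinoblastoma gene Rb1 at -0.85 and the cyclin gene Ccnd2 at -0.59. Of 30 genes of DNA methylation and silencing, 3 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.311): the chaperone gene Daxx (1.60) and Kdm1a (0.72) rose and Dnmt1 fell. Of 25 genes of extracellular matrix, 5 rose and 6 fell (7 and 6 adjusted over the list alone; adjusted p = 0.525), with Tnc falling from 2.38 ± 0.256 to 0.0141 ± 0.0125 and Postn, at 0 in WT and 0.257 ± 0.195 in sgMyc, at least 133-fold higher.

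Marker genes moved in the sgMyc set too. Of 8 fibroblast markers, Thy1 (1.86), Pdgfrb (2.66) and the proteoglycan gene Dcn (3.96) rose and none fell (6 rose adjusted over the list alone; median 2.26; camera adjusted p = 0.00643; adjusted p = 0.664 with an estimated correlation). The collagen gene Col3a1 had 229 FPKM in sgMyc replicates 1 and 2 and 25.1 in replicate 3, and Dcn 15.2, 14.6 and 0.67, the same order as the interferon-stimulated genes. Of 3 macrophage markers Cd14 rose (1.20; 1 adjusted over the list alone), and of 2 epithelial markers Cdh1 fell (1 adjusted over the list alone) from 0.0764 ± 0.0308 to 0.00453 ± 0.00785. The T cell marker Lck (-0.47, adjusted p = 0.338) and the 2 endothelial markers Cdh5 (-0.86, adjusted p = 0.12) and Pecam1 (-1.27, adjusted p = 0.225) did not pass. Of 13 mitochondrially encoded genes, 11 fell and none rose (12 fell adjusted over the list alone; median -0.66; camera adjusted p = 1.3e-07; adjusted p = 0.664 with an estimated correlation).

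The title links NAT10 to MYC, so the effects of both edits on mRNA were compared. The same 629 genes rose and the same 630 fell under both edits among 10867 genes tested in both sets, where independence would give 288 and 283 (two-sided Fisher's exact p = 2.9e-138 and 1.4e-133), and 185 genes moved in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.49 and a Spearman correlation of 0.479. Both edits were compared with unedited cells and without a control guide. A link between NAT10 and MYC thus cannot be told apart from a difference between parental and edited lines shared by both edits. Among the genes that rose most under both edits were the LIM domain gene Fhl1, U90926, Gm11884 and Rgs16, a regulator of G protein signalling. Fhl1 went from 0.0832 ± 0.0482 to 14.7 ± 0.242 FPKM in sgNAT10 and from 0.123 ± 0.0876 to 5.38 ± 6.44 in sgMyc. Those that fell most by the smaller of the 2 fitted log2 fold changes were Crabp1, Bgn, Ctsz, Rps6ka6 and Cyba. That order holds for log2(FPKM + 1), which shrinks genes of low expression, and by the ratio of mean FPKM others, such as Ppic, Sulf2 and Coro2a, fell more than Cyba in both sets. The shared count was 578 without sgMyc replicate 1, 547 without replicate 2 and 3744 without replicate 3, where 1166 genes moved in opposite directions and the share in the same direction was 76.3%, against 87.2% with all libraries.

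**Figure D3:**
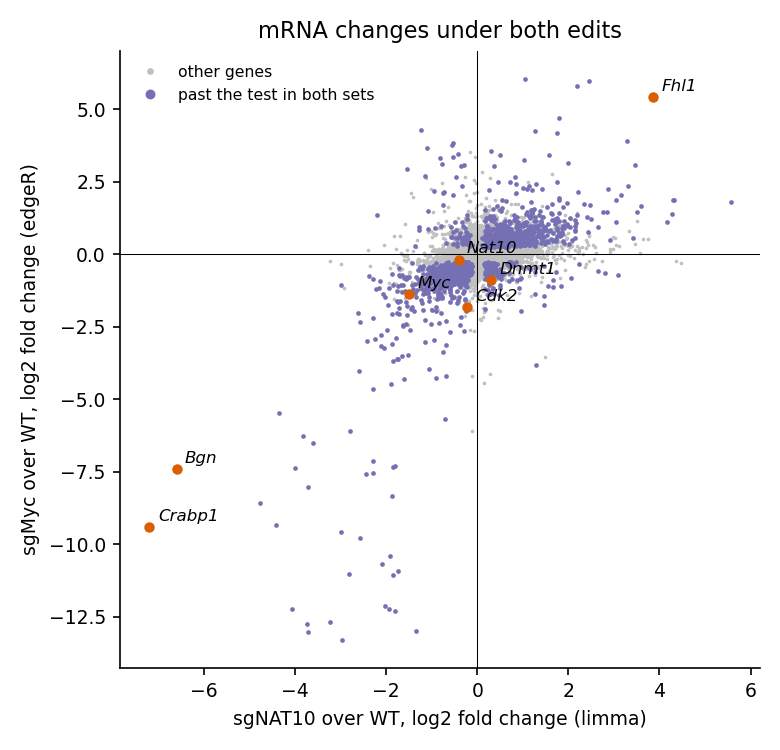
Log2 fold change of mRNA in sgNAT10 (horizontal axis, limma) and in sgMyc (vertical axis, edgeR) for the 10867 genes tested in both sets, with genes past the test in both coloured and 7 genes named. Fitted values of genes near 0 counts depend on the prior count of the test and are no bounds.

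The difference between the edits was tested directly with limma on both mRNA sets in 1 model, a test chosen after the data were seen. Cdk2 fell more in sgMyc (difference of log2 fold changes -1.53, SE 0.118, adjusted p = 0.000114), and Dnmt1, which rose in sgNAT10 and fell in sgMyc, differed by 1.18 (-1.18, SE 0.146, adjusted p = 0.00105). Myc (0.12, SE 0.264, adjusted p = 0.793) and Nat10 (0.21, SE 0.275, adjusted p = 0.646) showed no difference past the test. Of 10265 genes in that model 2153 differed. The 13 interferon-stimulated genes had a median of -0.30 in sgNAT10 and 2.63 in sgMyc (camera on the difference, adjusted p = 0.000134; adjusted p = 0.805 with an estimated correlation). Since the edits were measured against different WT libraries, the difference between the edits and that between the sets cannot be told apart.

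Most genes called in both mRNA and Ribo-seq of sgNAT10 moved the same way. Among 9200 genes tested in both assays, 161 rose and 112 fell in both, where independence would give 61.2 and 37.5 (two-sided Fisher's exact p = 3.0e-59 and 6.7e-48), and 2 moved in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.746 and a Spearman correlation of 0.651. At a threshold of 0.1 for the adjusted p the shared count was 581, against 273 at 0.05, and it was 733 with edgeR on recovered reads, added after the data were seen.

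**Figure D4:**
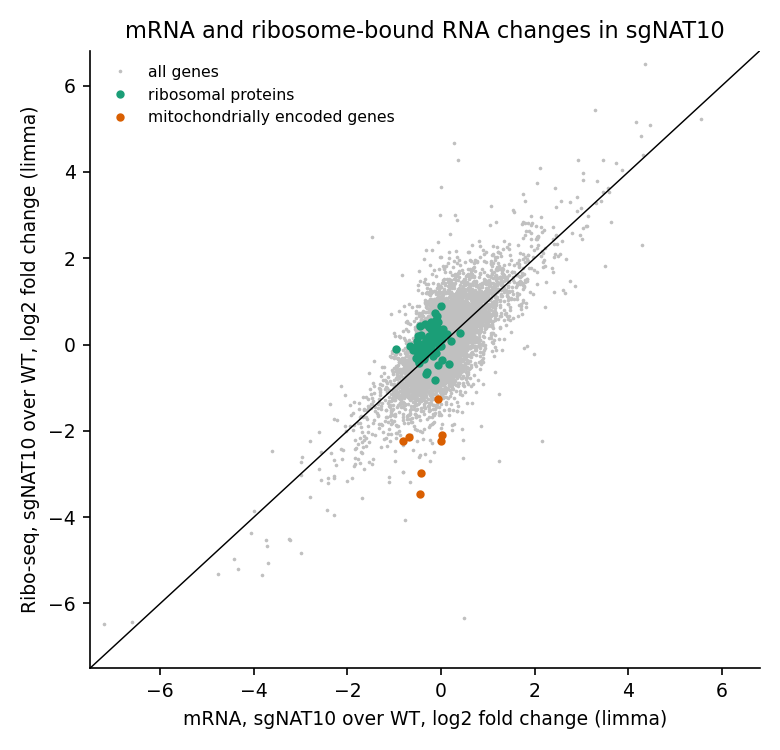
Log2 fold change in sgNAT10 of mRNA (horizontal axis) and of Ribo-seq footprints (vertical axis) for genes tested in both assays, with a line of equal change. The mitochondrially encoded genes lie below the line, with a median Ribo-seq change of -2.24, and most ribosomal protein genes lie above it.

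The last data set asked where acetylated RNA differed between WT and sgNAT10. The deposited peak list, on coordinates of the mouse build mm10, held 1358 peaks, of which 887 in 728 genes passed the authors' false discovery rate at 0.05. Read as sgNAT10 over WT, an order that the header does not state, 371 peaks were lower and 516 higher, with a median length of 208 bp. In the opposite order every direction given for a peak turns, with 516 lower and 371 higher, those of Myc higher, and the lowest peaks the highest. Each genotype had a single precipitated library, so no replicate error can be given. In coding sequence 233 peaks were lower and 315 higher, in exons of no stated class 77 and 126, in the 5' untranslated region 27 and 44, in the 3' untranslated region 34 and 30, and 1 higher peak lay at a start codon. Myc held 3 peaks, all lower: -2.87 on the log2 scale on chromosome 15 from 61985809 to 61987159 in the deposited class of 3' untranslated region, although on the plus strand it lies before the other 2, -1.57 from 61987486 to 61987845 and -0.66 from 61989568 to 61989747 in coding sequence. Dnmt1 held a peak at 0.29 on chromosome 9 from 20938138 to 20941465 and one at -0.54 from 20927119 to 20936571, both in coding sequence, and the list held none in Nat10 or Cdk2. Among the lowest peaks were those in the formin gene Diaph2 (-8.15), the cytokine receptor gene Il6st (-7.80), the transcription factor gene Creb5 (-6.63) and the histone demethylase gene Kdm6b (-6.40). The highest lay in the calcium channel gene Itpr1 (6.11), Cdk10 (5.94), the selenoprotein gene Selenos (5.44), the kinase gene Stk24 (5.21) and the amino acid transporter gene Slc36a1 (5.13). With an absolute log2 fold of at least 2, 201 peaks remained and the balance turned, with 108 lower and 93 higher, while 451 were 200 bp or longer (185 lower and 266 higher).

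In the fixed lists peaks are given as sgNAT10 over WT, and all directions turn in the opposite order, where all 8 peaks of oxidative phosphorylation, 7 of 8 of glycolysis and 10 of 14 of extracellular matrix are lower. Of 75 ribosomal protein genes, 42 held 47 peaks, 17 lower and 30 higher, and 13 of the MYC targets held 15 peaks, 6 lower and 9 higher. All 8 peaks in genes of oxidative phosphorylation were higher, as were 7 of 8 in glycolysis and 10 of 14 in extracellular matrix. Among 7 peaks in genes of DNA methylation and silencing 5 were higher. Bst2 and Isg20 held the 2 peaks of the interferon-stimulated genes, both lower. The MHC class I genes held 3 lower and 2 higher peaks, the ATF4 and stress genes 4 lower and 1 higher, ribosome biogenesis 2 lower and 3 higher, nucleic acid sensing 1 of each, and chemokines and cytokines 1 lower and 2 higher. All peaks were higher in G1/S (2), G2/M (3), CDK regulators (2) and the fibroblast marker Col1a2 (3), and the other lists held none. No test was made of these counts.

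Genes with peaks of either direction rose more often than expected in sgNAT10 mRNA. In the opposite order of the fold, the genes described with a higher peak are those with a lower peak. The 369 tested genes with a higher peak had a median mRNA change of 0.07 on the log2 scale, at the 99.6th percentile of 10000 random gene lists matched on expression, and 168 of them were among the genes that rose, where 125 were expected (two-sided Fisher's exact p = 2.3e-06). The 276 genes with a lower peak had a median of 0.05, at the 91.5th percentile, and 114 rose where 93.1 were expected (p = 0.0082, same exact test), an excess lost with a minimum mean of 5 FPKM (100 against 94.2 expected, p = 0.461, same exact test). In Ribo-seq the genes with a higher peak had a median of 0.04 (percentile 99.5) and 25 rose where 6.36 were expected (p = 3.9e-09, same exact test; 28 where 10.6 were expected with that minimum), and those with a lower peak a median of 0.01 (percentile 74.0). In translational efficiency the medians were -0.02 (percentile 29.0) for genes with a higher peak and 0.00 (percentile 71.3) for those with a lower peak. Of the latter 3 rose, among them Rps19 and Rack1, where 0.402 were expected (p = 0.00672, same exact test), and Ybx1 and Odc1 fell where 0.287 were expected (p = 0.0317, same exact test). With the minimum of 5 FPKM 4 rose where 0.416 were expected (p = 0.000529, same exact test). Restricted to peaks with an absolute log2 fold of at least 2, the genes with a higher peak had a median of -0.18 in translational efficiency (75 genes, percentile 0.13) and 0.0857 in Ribo-seq (percentile 92.0, within the range of random lists). In Ribo-seq 4 of these 76 genes rose where 1.38 were expected (p = 0.0489, same exact test) and 4 fell where 0.971 were expected (p = 0.0161, same exact test). Of 89 genes with a lower peak at that fold, 0 rose and 0 fell in translational efficiency, where 0.135 and 0.0967 were expected. Acetylated RNA peaks are found more readily in abundant RNA, and the random lists were matched in 10 bins of mean expression while the Fisher tests were not matched.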

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

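The tests of the difference between the edits and of what lies behind the interferon-stimulated genes were chosen only after the result was seen, while the splits of the libraries were planned.

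Effects of the edits differed between the sgNAT10 and sgMyc mRNA sets by a test of the difference itself, with the sets and the edits confounded. Cdk2 differed by -1.53 and Dnmt1 by -1.18 (sgMyc minus sgNAT10, log2). The list medians of that difference were 2.69 for 13 interferon-stimulated genes (camera adjusted p = 0.000134), -0.30 for G1/S and DNA replication (0.0333), -0.36 for G2/M (0.00113), 0.12 for ribosome biogenesis (0.0245), 0.0842 for ribosomal proteins (0.0161), -0.48 for extracellular matrix (0.00113) and -0.60 for mitochondrially encoded genes (0.0333). None of the 7 lists passed with an estimated correlation, where the adjusted p was 0.121 for extracellular matrix and 0.805 for the other 6.

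The interferon-stimulated genes were highest in sgMyc replicates 1 and 2. Macrophages in those libraries are argued against by Lyz2, Fcer1g, C1qb and Itgam, which together had at most 32 counts in any library and 6 and 5 in replicates 1 and 2, although other macrophage genes were highest there. Mpeg1 had 537 and 552 counts there, Cd68 had 7.17, 6.85 and 2.38 FPKM in sgMyc replicates 1, 2 and 3 and at most 3.93 in WT, and Cd14 had 22.1, 20.6 and 13.5 FPKM and at most 8.76 in WT. T cells are argued against by Trac, Cd4, Cd8a, Cd5 and Cd52, together at most 15 counts in any library. The T cell marker Lck was left out of that sum. It had 99, 71 and 93 counts in WT and 92, 65 and 54 in sgMyc replicates 1, 2 and 3, so it did not rise with the interferon-stimulated genes. Other genes looked for, such as Cd3e and Ptprc, are not listed in the table and exclude nothing. Also argued against are normal fibroblasts, whose abundant Col1a1 reached at most 0.46 FPKM in those libraries, where Col3a1 had 229 FPKM. Whether the level of Myc mRNA accounts for the pattern could not be decided. In the sgNAT10 set Myc fell by 1.49 on the log2 scale and the 13 tested genes of the list had a median of -0.298. That set differs in its edit and its WT libraries. Within the sgMyc set Myc was lower where the list was highest, at 21.1 and 20.9 FPKM in replicates 1 and 2 and 34.1 in replicate 3. A different clone, guide or degree of loss of MYC protein in replicates 1 and 2 remains a candidate explanation, which no table of these data decides.

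The 6 libraries of the sgMyc set make 10 splits into groups of 3, so a share under 0.05 cannot be had. The real split gave 2682 genes, and the highest other split 1, so that 1 of 10 splits gave as many. For gene lists the real split gave 9 lists past the threshold and the highest other 15, so that 4 of 10 gave as many. The splits that put sgMyc replicate 3 with WT libraries gave 12, 15 and 14 lists, which points to a structure of the samples.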

How the results depend on the processing

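The tests by edgeR on recovered reads, the thinning of reads and the overlaps without each sgMyc replicate were chosen only after the result was seen; all other alternatives were planned. Named genes kept direction and side of the threshold in all 639 values of the sgNAT10 mRNA set, in 366 of 528 in Ribo-seq, 616 of 703 in translational efficiency and 516 of 761 in the sgMyc set. The sign turned in 1 value of each of the last 3, Dnmt1, Myc and Nat10, none past the test before or after. Gene list tests kept both in 152 of 179, 159 of 179, 214 of 251 and 174 of 216 values. Their direction turned in 11, 8, 30 and 5 values, of which 1 was past the threshold, the ATF4 and stress list in sgNAT10 mRNA under fry (adjusted p = 0.0325). The number of called genes in sgNAT10 mRNA stayed within 1.5 times 7431 under all alternatives, from 5096 to 9250. The cause was not tested for the changes that follow, unless named.

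In Ribo-seq 300 genes became 87 without a trend in the variance, 777 with edgeR on recovered reads, and 0 to 9 with a library left out, where fewer libraries remain. In translational efficiency 24 became 299 with separate fits per assay and 3 to 640 with a library left out, and with the replicate number as a block 1 gene passed. In the sgMyc set 2682 became 1419 with a mean FPKM of at least 5, where fewer genes are tested, 1783 with limma without a trend, 949 with the replicate block, and 680 to 9368 with a library left out.

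The 1259 genes shared by both edits became 1905 at an adjusted p under 0.1, 203 with an absolute log2 fold change of at least 1, 807 with a mean FPKM of at least 5, and 547 to 3744 without 1 sgMyc replicate. The 273 genes shared by mRNA and Ribo-seq became 581 at an adjusted p under 0.1 and 733 with recovered reads. The 887 acRIP peaks became 201 at an absolute log2 fold of at least 2, where 371 lower and 516 higher turned to 108 lower and 93 higher, and 451 at 200 bp or longer. At that stricter fold, genes with a higher peak had medians of 0.0857 in Ribo-seq and -0.18 in translational efficiency. With an estimated correlation camera called 0 lists in each of the 4 comparisons, and fry called 12 in sgNAT10 mRNA, 8 in Ribo-seq, 7 in translational efficiency and 1 in the sgMyc set, against 4, 4, 2 and 9. With a library left out, camera called 2 to 5 lists in Ribo-seq and 5 to 15 in the sgMyc set.

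Depth limited Ribo-seq in part. With mRNA reads thinned to the depth of Ribo-seq, edgeR called 5300 genes (5253 to 5315 over 5 draws), against 765 in Ribo-seq itself among the same 10736 genes, so depth alone did not give the lower number. Replicates spread more in Ribo-seq, where 34.3% of genes in the WT pair lay past the limit for sampling alone.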

Other observations

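The gene ontology terms, the genes near 0 in both mRNA sets and all tests below were chosen only after the result was seen, except the count of genes with a neighbour that fell and the test of digestion, which were written before.

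Gene ontology terms described the same called genes in another way. Several terms share their theme with the fixed lists, such as rRNA processing, translation, defense response to virus and the response to interferon-beta. They are no separate support for those lists. In sgNAT10 mRNA the falling genes held 96 of 143 genes of rRNA processing (44.3 expected, adjusted p = 1.0e-15, one-sided exact hypergeometric test) and 145 of 266 of translation (5.5e-13, same test), and the rising genes 137 of 267 of the cell surface (8.1e-05, same test) and 77 of 133 of focal adhesion (8.2e-05, same test). In Ribo-seq the rising genes held 22 of 178 of cell adhesion (3.26 expected, 2.7e-09, same test), while collagen-containing extracellular matrix held 18 of 137 rising (6.4e-08, same test) and 13 of 137 falling genes (3.9e-05, same test). In the sgMyc set the rising genes held 54 of 157 genes of defense response to virus (13.2 expected, adjusted p = 9.4e-17, same exact test) and 23 of 51 of the response to interferon-beta (2.5e-09, same test). The falling genes held 14 of 25 of triplet codon-amino acid adaptor activity, all 14 of them mitochondrial transfer RNA genes such as mt-Tl1 and mt-Ta (2.55 expected, 6.1e-05, same exact test).

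Genes silent in the edited cells were shared. Among 10867 genes, 30 with at least 5 FPKM in WT fell at least 10-fold in sgNAT10 and 18 in sgMyc, and 11 were in both lists, namely Crabp1, Bgn, Ctsz, Rps6ka6, Cyba, Ppic, Sulf2, Tspan6, Coro2a, Pmp22 and Tex13b. Chance overlap of independent lists is argued against by these 11, where 0.0497 were expected. Of 40 genes at least 10-fold higher in sgNAT10 and 17 in sgMyc, with at least 5 FPKM there, 1 was in both, Fhl1 (0.0626 expected, p = 0.0608, two-sided Fisher's exact test). Loss of a stretch of DNA that reached from each gene to a nearest expressed neighbour is argued against for the set. Of the 11 genes, 2 had such a neighbour that fell by 1 or more, namely Bgn and Coro2a. For Bgn a loss that reached a neighbour is argued against in sgMyc, where Haus7 and Dusp9 had log2 fold changes of 0.315 and 0.321, but cannot be told apart in sgNAT10, where Dusp9 fell by 2.05 (-2.05). For Coro2a it cannot be told apart in either set, since its neighbour Galnt12 had -11.04 in sgMyc and -1.85 in sgNAT10. A deletion that stops short of the nearest expressed neighbours stays open. Some of these lay far away, such as Sh3bgrl and Apool at 2200242 and 878975 bp from Rps6ka6, measured between gene midpoints. Without a control-guide library, a difference between the parental and the edited lines shared by both edits cannot be told apart from an effect of the edits. No gene exceeded 6.37% of its WT mean in any edited library. The genes were chosen for low means in the edited libraries of both sets, so that level cannot decide the question.

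Footprints of mitochondrially encoded genes were lower in sgNAT10. A fall of the mitochondrial transcripts as the whole cause is argued against by the change relative to mRNA, a median of -2.10. The transcripts did fall, with a median of -0.43 in mRNA, so a share of theirs stays open. A lower yield of mitochondrial fragments of every kind as the whole cause is argued against by the mitochondrial ribosomal RNAs. Their larger fall was -0.875 in mt-Rnr1 (SE 0.21), against a median of -2.24 in the protein-coding footprints, which leaves a partial loss of yield open. A difference in nuclease digestion or fragment size selection could not be told apart from lower mitochondrial translation, since 0 Ribo-seq libraries have fragment lengths in the deposited tables.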
